A study of Drosophila melanogaster with 44 samples.

How the data were processed

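Each sample was 15 adult females of Drosophila melanogaster, 0-24 h old, grown at 25 °C. Total RNA was isolated with TRIzol and RNeasy and labelled with biotin for Affymetrix arrays, 1 array per sample. The deposited values are log2 expression values per probe set that the authors obtained with RMA, which corrects background, normalises between arrays and summarises probes; the version of RMA, the genome build and the annotation are not given in the sources used here. The labels do not state the log base, and the range of values, 2.58 to 14.66, and the close array medians are those of RMA on the log2 scale. The number of arrays limits the precision; no counts lie behind the values. RMA compresses low values, so a fold change of a dim gene is a lower estimate of the change.

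The array holds 18952 probe sets. The annotation gave 1 gene symbol to 13647, several genes to 402 and none to 4903. Of these, 13534 were matched by gene identifier to Release 6 genes with a place on a chromosome arm, which gave 11884 genes. Release 6 was used for names, gene order and gene span only. For the 728 tested genes with more than 1 probe set, the one with the highest mean over all arrays was taken. The 7476 genes with a mean of at least 6 were tested, 292 of them (3.91%) inside the 7 intervals.

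Genotypes and replicates came from the labels, which call the replicates biological. The 6 wild-type and 19 single-deletion arrays entered 1 fit of group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a trend on the mean; contrasts were the mean of the 7 deletions against wild type, each deletion against wild type, and an F test among the 7. The doubles, taken as 1 group, were compared with singles weighted by how often each deletion occurs in the doubles. For additivity, the departure of each double genotype from the sum of its single deletions was averaged over the 19 genotypes, with the spread taken from the replicated genotypes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and genes inside the intervals concerned were left out. The p-values treat the arrays of a group as independent flies.

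Each interval was mapped as the highest-scoring run of neighbouring genes on the arm in the deletion's name, from carriers minus non-carriers over all 44 arrays, with an offset of 0.3 and a score limit of 0.7 per gene. Mapping from double arrays alone gave the same ends except for ED3, which ended at UK114, and mapping from single arrays alone gave the same except for ED5071, which began at CG40198. The 1-copy level of an array is the median over interval genes of its log2 value minus the wild-type mean. Group differences used exact permutation tests, and correlations used permutation tests with 100000 resamples (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; figures with matplotlib 3.10.9).

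There were 27 gene lists, fixed before the data were examined, as were the design, the comparisons and a set of alternative settings: digestive serine proteases, other proteases, proteasome, ubiquitin, other digestive genes, antimicrobial peptides, Turandot, heat shock and chaperones, endoplasmic reticulum folding, detoxification and antioxidants, oxidative phosphorylation, mitochondrial and cytosolic ribosomal proteins, ribosome biogenesis, autophagy, DNA damage and apoptosis, dosage compensation, eggshell and yolk, germline, muscle, neuron, photoreceptor, hemocyte, cuticle, larval fat body, testis and male accessory gland. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. None of the 9 calls with the preset correlation was called with the estimated correlation or by fry, which gave adjusted p = 0.0709 for the digestive proteases, other digestive genes and the mitochondrial ribosome and 0.0735 for the proteasome.

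Genes were named by a rule fixed before the data were examined. For the first comparison it takes the 12 largest rises and 12 largest falls that passed and moved the same way in the means of all 7 deletions, and up to 4 members with the largest difference of each called list. For each deletion it takes the 2 largest rises and 2 largest falls that passed, the first and last gene of the interval, and the 2 interval genes with the largest and the 2 with the smallest difference; for the F test it takes the 6 largest F. Other genes were named after their values were seen, and the text says so. The gene white, also in the rule, is not among the probe sets with 1 gene and was not analysed here.

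The methods were tested on simulated data of the same layout. With 100 genes changed by 0.5 and 100 by 1 on the log2 scale, the comparison of single deletions with wild type recovered 57 and 91 with 5 false calls, a single deletion of 3 arrays 36 and 72 with 4, the F test 10 and 65 with 8, doubles against singles 86 and 98 with 9, and non-additivity 41 and 82 with 7. The list test recovered the 1 shifted list with 0 false among 23, and the mapping placed 374 of 400 interval ends exactly and 397 within 1 gene. Simulated genes were drawn independently of each other, without the correlation between genes of the real arrays. The false rate of the list test in the real data is therefore not given by this. There, 67 of 100 splits of the arrays called at least as many lists as the real 9.

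Alternative settings fixed at the same time were recentring each array on arms X and 3L, which carry none of the deletions; no filter and stricter filters of 7 or 8; the mean of all probe sets of a gene; no trend; replicate number as a block; a fit of 1 deletion and wild type only; a threshold of 1.5-fold; other mappings of the intervals, intervals without the 2 outermost genes per side and the mean over genes; and leaving out each array in turn. Chosen after seeing the data were leaving out wild-type replicates 4 and 5 or the 2 double arrays of shifted mean, array numbers (up to 26, and from 27) apart or as a block, the germline list as a covariate, non-carriers as the reference, levels centred within each interval, and an additive fit with 1 term per deletion over all 44 arrays, in which the lists and the genes of the vacuolar proton pump, taken by symbol, were tested with camera for each deletion. Replicate number is no main term, since correlations between arrays of the same number varied widely, from -0.730 to 0.849. In the 5 deletions with 3 arrays the number does follow runs of array numbers. What such a run shares is left in the spread of the main fit. Probe sets with several genes or no name were left out.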

Results

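Gene expression was measured in adult female Drosophila melanogaster in which 1 or 2 chromosome segments were present in a single copy. The segments were removed by 7 deficiencies, chromosomes that lack a stretch of neighbouring genes: Df(2L)ED4559 and Df(2L)ED3 on arm 2L, Df(2R)ED1612 and Df(2R)ED1770 on arm 2R, and Df(3R)ED5071, Df(3R)ED7665 and Df(3R)ED10953 on arm 3R, called below by their ED names. The 44 Affymetrix arrays comprised 6 of wild type, 19 of flies with 1 deletion and 19 of flies with 2 deletions. The single deletions had 3 arrays each, except ED5071 and ED7665 with 2 each, and each of the 19 double combinations had 1 array. The number of arrays limits the precision. Array medians lay between 5.50 and 5.73 on the log2 scale, and correlations between arrays between 0.950 and 0.997. Of 11884 genes, 7476 had a mean of at least 6 and were tested.

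The ovary differed between arrays. Chorion gene Cp15, an eggshell gene of late follicle cells, had a log2 value of 14.10 in wild-type replicate 4 and 13.48 in replicate 5, against 4.13 in replicate 2, and Cp36 stood at 13.90 and 13.20 against 6.12. The list of eggshell and yolk genes lay 2.77 and 2.26 above the wild-type mean in replicates 4 and 5 and between -2.04 and -0.40 in the other wild-type arrays. The germline list followed the same order, with 1.37 and 0.99 in those 2 arrays. The leading component of variation over all arrays held 41% of the variance, and its correlation with the germline list was 0.968. Array numbers in the labels also split the deletion arrays: germline genes lay at -0.36 ± 0.37 (SD, n = 10) in single-deletion arrays numbered up to 26 and at 0.59 ± 0.26 (SD, n = 9) in those numbered from 27. The 6 wild-type arrays had numbers 1 to 6, and every deletion array had a number of 7 or higher. Array order therefore cannot be told apart from deletion in any comparison with wild type.

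Genes inside the deleted intervals are the subject of the question of buffering in the series title. Their median over an interval was lower in every carrier, in most to a little above the 50% that 1 of 2 copies would give with no buffering. Os-C, an olfactory-specific gene, differed by -2.75 in ED7665, to 6.25 ± 0.07 (SD, n = 2). Neprilysin-like Nepl11 in ED5071 stood at 7.08 ± 0.09 (SD, n = 2) against 9.12 ± 0.52 (SD, n = 6). At the other end, Vha16-1, a subunit of the vacuolar proton pump, differed by -0.21 in ED1612, the ryanodine receptor gene RyR by -0.18 in ED1770, and CG31523 by 0.15 in ED5071. With all carriers averaged, 87 of 292 interval genes were at or below -1 against wild type, 193 lay between -1 and -0.3, and 12 lay above -0.3. Against arrays with 2 copies of the interval these counts were 66, 223 and 3, the last being CG4168 (-0.13), ana2 (-0.16) and CG17264 (-0.18), named after their values were seen.

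The intervals were mapped from the expression values as runs of lower neighbours. ED4559 ran from Ccdc85 to Pgant4 (39 tested genes), ED3 from noc to CG15263 (22), ED1612 from bin3 to Tsp42El (50), ED1770 from Acsl to Gnptab (60), ED5071 from beta-Man to Ubc6 (51), ED7665 from Alh to CG7910 (51), and ED10953 from Alg9 to CG31098 (19). In the single carriers the genes at the ends differed from wild type by -0.67 for Ccdc85 and -0.50 for Pgant4, -0.50 for noc and -1.33 for CG15263, -1.13 for bin3 and -0.89 for Tsp42El, and -0.39 for Acsl and -1.05 for Gnptab. On arm 3R they were -0.54 for beta-Man and -1.32 for Ubc6, -0.52 for Alh and 0.05 for CG7910, and -0.87 for Alg9 and -0.81 for CG31098. The largest differences within the remaining intervals were CG12795 (-1.34) and CG33281 (-1.24) in ED4559, CG34166 (-1.98) and UK114 (-1.43) in ED3, CG17266 (-1.51) and Tsp42Ek (-1.38) in ED1612, UQCR-11L (-1.36) and Ance-4 (-1.23) in ED1770, and Nup37 (-1.16) and CG31104 (-1.14) in ED10953, beside CG1092 (-1.90) in ED5071 and alpha-Est2 (-1.80) in ED7665. The smallest were CG17264 (-0.08) and FASN2 (-0.03) in ED4559, CG4168 (-0.08) and wwk (-0.01) in ED3, Tsp42Ee (-0.27) in ED1612, rpk (-0.14) in ED5071, CG18748 (-0.22) in ED7665, and CG11892 (-0.45) and CG11878 (-0.29) in ED10953.

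The median over interval genes, taken per array as log2 minus the wild-type mean, was -0.82 ± 0.04 (SD, n = 3) for ED4559, -0.86 ± 0.08 (n = 3) for ED3, -0.85 ± 0.07 (n = 3) for ED1612 and -0.87 ± 0.07 (n = 3) for ED1770. It was -0.80 ± 0.03 (n = 2) for ED5071, -0.85 ± 0.02 (n = 2) for ED7665 and -0.85 ± 0.07 (n = 3) for ED10953. These levels correspond to 54.7% to 57.3% of wild type. Each group of 3 carriers differed from wild type with p = 0.0119 and each group of 2 with p = 0.0357 (exact two-sided permutation tests), the smallest these group sizes allow. The intervals were chosen as genes lower in carriers over all arrays, the tested ones among them, so these p-values are not independent of the mapping. Mapping from double arrays alone, which holds none of the tested arrays, gave the same ends except for ED3. The mean of the 7 levels was -0.84 (SD 0.02, 55.7% of wild type). All 7 levels share the same 6 wild-type arrays, and the compression of low values by RMA moves levels in the same direction as buffering would, so no test against -1 is given. All 19 single-deletion arrays and 53 of the 57 carrier values lay above -1. Carrier values ran from -1.10 to -0.73, and the 251 values of arrays with 2 copies of an interval from -0.37 to 0.26. Over genes, the pooled median was -0.88 (95% bootstrap interval -0.92 to -0.84, 54.2% of wild type, 292 genes that are not independent replicates). Levels did not differ detectably among the 7 deletions (permutation p = 0.889).

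**Figure D1:**
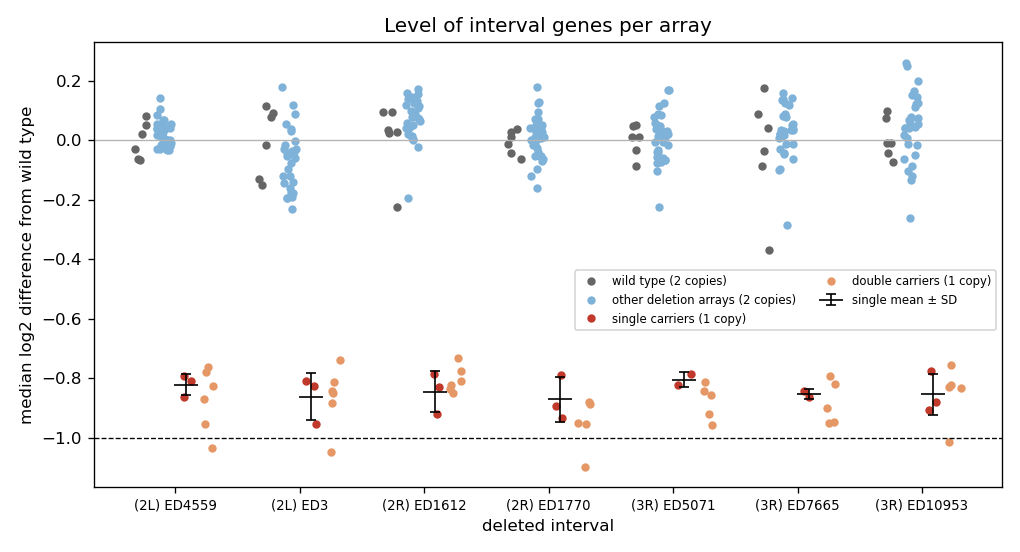
Median log2 difference from wild type of the genes in each deleted interval (y axis), 1 point per array, by interval (x axis) and by copy number, with the mean and SD of the single carriers and a dashed line at -1. Carrier values lie between -1.10 and -0.73, apart from the 2-copy values between -0.37 and 0.26.

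A second deleted segment did not detectably change the level of the first. Double carriers lay at -0.87 for ED4559 (n = 6), -0.86 for ED3 (n = 6), -0.80 for ED1612 (n = 6), -0.95 for ED1770 (n = 5), -0.88 for ED5071 (n = 5), -0.88 for ED7665 (n = 5) and -0.85 for ED10953 (n = 5). The mean difference, double minus single, was -0.03 (95% interval -0.07 to 0.01), with doubles higher in 3 of 7 deletions (exact two-sided sign-flip permutation p = 0.188). Each double array enters the differences of both its deletions, so the 7 differences are not independent, as the test and interval assume. Among the doubles are 2 arrays of shifted mean, ED4559 with ED1770 and ED4559 with ED1612. Their mean levels over interval genes were -1.06 and -0.73.

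Longer interval genes kept a higher level relative to wild type. The shortest genes by span (median 1457.5 bp, 98 genes) had a median of 51.7% of wild type, the middle group (median 2733.5 bp, 96 genes) 52.9% and the longest (median 9412 bp, 98 genes) 60%. Across 292 genes, Spearman's rho between level and span was 0.372 and Pearson's r 0.389, each with a two-sided permutation p of 1e-05, the smallest the resamples allow. Genes are not independent replicates. Without the filter on low values this rho was -0.0646 (permutation p = 0.160, 476 genes). Within intervals rho was 0.677 for ED3 (adjusted p = 0.0056, permutation test), 0.507 for ED5071 (0.00182), 0.393 for ED7665 (0.0166), 0.331 for ED1770 (0.0282), 0.322 for ED1612 (0.0538), 0.236 for ED4559 (0.255) and 0.00877 for ED10953 (0.974). Adjustment covered the 14 within-interval relations with length and expression.

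The same genes showed a relation with length at 2 copies. In deletion arrays that did not carry the interval, the medians against wild type were -0.07, 0.01 and 0.12 from the shortest to the longest group, and rho was 0.40 (permutation p = 1e-05, the smallest possible). Measured against all arrays with 2 copies, wild type among them, the 1-copy levels were 53.9%, 54.1% and 56.1% and rho was 0.121 (p = 0.0396). Against the 2-copy deletion arrays alone, with wild type removed from both sides, rho was 0.0377 (p = 0.520). Expression level itself had rho -0.0779 (p = 0.185) and r -0.0315 (p = 0.593) with the 1-copy level, and -0.401 (adjusted p = 0.0166, permutation test) within ED7665. In permutation tests the pooled relation with expression passed the threshold with the mean of all probe sets of a gene (-0.136, p = 0.0211) and with no filter (-0.677, p = 1e-05, the smallest possible).

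**Figure D2:**
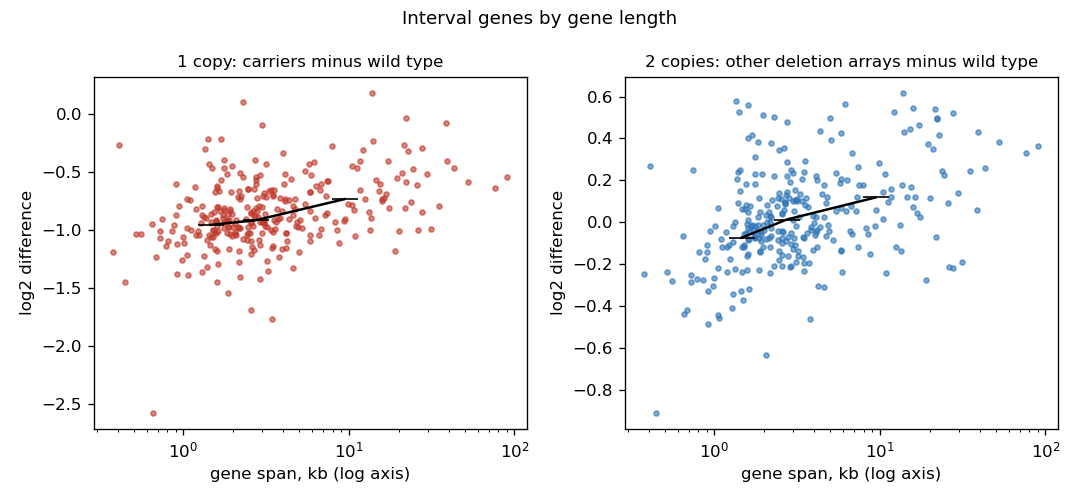
Log2 difference from wild type of each interval gene (y axis) against gene span in kb (log axis), for carriers with 1 copy (left) and for other deletion arrays with 2 copies (right); black marks join the medians of the length groups. Medians run from -0.95 to -0.74 at 1 copy and from -0.07 to 0.12 at 2 copies.

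Outside the intervals, the mean of the 7 single deletions was compared with wild type to ask what carrying any of these segments in 1 copy has in common. A difference in stock background between deletion flies and wild type was not tested. It cannot be told apart from the lost copy, here or for each deletion against wild type. Nor can array order, since all wild-type arrays are numbered below all deletion arrays. Syt7 on chromosome 4, a synaptotagmin of vesicle trafficking, rose by 2.51 ± 0.25 (SE; 5.68-fold; 4.56 ± 0.17, SD, n = 6, in wild type), and CG14957 rose by 2.06 ± 0.36 (4.17-fold). Smvt, a multivitamin transporter, rose by 0.85 ± 0.16, net, a transcription factor of wing vein patterning, by 0.85 ± 0.19, and yellow-d, of the yellow family, by 0.80 ± 0.18. Mtk, the antimicrobial peptide metchnikowin, fell by 1.67 ± 0.39, and Zip89B, a zinc transporter, fell by 0.65 ± 0.11. Membrin, a Golgi SNARE, fell by 0.47 ± 0.08, Uch, a ubiquitin hydrolase, fell by 0.46 ± 0.09, and PSMG1, a proteasome assembly chaperone, fell by 0.37 ± 0.06.

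Adjusted p was 3.58e-05 for Syt7, 0.0126 for CG14957, Smvt, Zip89B, Membrin and PSMG1, 0.0203 for Uch, 0.0331 for net, 0.0296 for yellow-d and 0.0386 for Mtk (limma). In all, 92 of 7184 genes passed (67 higher, 25 lower; 1513 at an unadjusted p under 0.05). The other named rises were CG4835 (1.27, adjusted p = 0.0331), CG9897 (1.19, 0.0129), CG10477 (1.03, 0.0296), CG15784 (0.99, 0.0126), salt (0.87, 0.0126), CG10560 (0.82, 0.00506) and CG34043 (0.79, 0.00388). The other named falls were CG13737 (-0.68, 0.0450), CG32243 (-0.47, 0.0126), CG3021 (-0.44, 0.0296), Ing5, of the inhibitor of growth family (-0.38, 0.0493), CG5828 (-0.36, 0.0203), Ibf2, an insulator-binding factor (-0.35, 0.0271), and CG2147 (-0.35, 0.0296). All 24 moved the same way in the means of all 7 deletions, by the rule that chose them. The count was 20 without wild-type replicate 4, 44, 50 and 56 without replicates 1, 2 and 6, 38 without ED5071 replicate 1, 36 without ED7665 replicate 2, and 160 without ED3 replicate 2. It was 3 among arrays numbered up to 26, 6 with array number as a block, 156 without wild-type replicates 4 and 5 (46 of them among the 92), and 1487 with the germline list as a covariate; Syt7 was the only one of the 24 that kept its call in all 35 settings. Ing5 kept it in 7 of 35, CG13737 in 10 of 33, Mtk in 17 of 35, net in 24 of 34, CG4835 in 25 of 35, CG10477 and CG2147 in 26 each, yellow-d and CG3021 in 27 each, Ibf2 in 29, Uch and CG5828 in 31 each, and the others in all but 1 or 2.

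Digestive serine proteases, enzymes of trypsin and chymotrypsin type and mostly of the gut, lay higher in single-deletion arrays than in wild type, and genes of the mitochondrial ribosome and the proteasome lay lower. Of 34 protease genes tested, 2 rose, Ser12 by 0.64 ± 0.13 (SE, adjusted p = 0.0226) and Send1, a spermathecal endopeptidase, by 0.58 ± 0.14 (0.0490), both named after their values were seen; 3 rose adjusted over the list alone, and the list mean was 0.59. The members with the largest differences did not pass: Jon99Fi 2.55 ± 0.93 (adjusted p = 0.137), Jon65Ai 1.94 ± 0.79 (0.171), epsilonTry 1.45 ± 0.59 (0.171) and Jon74E 1.22 ± 0.48 (0.153). Other digestive genes had a list mean of 0.24, with 1 of 33 higher, the mucin gene Muc11A by 0.74 ± 0.12 (adjusted p = 0.0126, named after its value was seen), and 8 higher adjusted over the list alone. Peritrophin-15b (1.06), Npc2f (0.93), Peritrophin-15a (0.87) and Npc2e (0.80), the largest differences there, did not pass over all genes tested, and Npc2f did within the list (adjusted p = 0.0205). Camera called the proteases with adjusted p = 1.89e-06 and the other digestive genes with 0.00948; both had adjusted p = 0.607 with an estimated correlation. Proteases lay at 0.30 ± 0.43 (SD, n = 10) above wild type in single arrays numbered up to 26 and at 0.83 ± 0.14 (SD, n = 9) in those from 27, while germline genes lay at -0.36 and 0.59; without wild-type replicates 4 and 5 the list mean was 0.93, and with the array-number block 0.33. The means of single carriers ran from 0.20 in ED10953 (n = 3) to 0.91 in ED5071 (n = 2). In an additive fit over all 44 arrays with the array-number block, chosen after the data were seen, the list was higher in ED1612 (0.20), ED4559 (0.16) and ED1770 (0.12), camera adjusted p = 0.00200, 0.00200 and 0.0239, and at least 0.926 with an estimated correlation. It was not called in ED7665 (0.0020), ED5071 (-0.013), ED3 (-0.033) or ED10953 (-0.089).

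Mitochondrial ribosomal proteins had a list mean of -0.18, with 1 of 70 lower over all genes tested, mRpL12 by -0.24 ± 0.06 (SE, adjusted p = 0.0479, named after its value was seen), and 19 lower adjusted over the list alone. mRpL51 (-0.40 ± 0.14, SE), mRpL36 (-0.39 ± 0.13) and mRpL32 (-0.36 ± 0.11) passed within the list, with adjusted p of 0.0454 each, and mRpL52 (-0.35 ± 0.14) did not. Proteasome genes had a list mean of -0.20, with 1 of 29 lower, PSMG1, and 13 lower adjusted over the list alone, among them Prosalpha6 (-0.33 ± 0.09), Rpn12 (-0.30 ± 0.09) and Rpn11 (-0.29 ± 0.11). Camera gave adjusted p = 1.37e-15 for the mitochondrial ribosome and 9.7e-11 for the proteasome, and adjusted p = 0.607 for each with an estimated correlation. The 2 array-number groups of single arrays stood at -0.08 ± 0.08 (SD, n = 10) and -0.29 ± 0.11 (SD, n = 9) for the mitochondrial ribosome and at -0.16 ± 0.14 and -0.23 ± 0.14 for the proteasome. With the array-number block the list means were -0.04 and -0.16. In the additive fit with that block the mitochondrial ribosome went both ways: it was lower in ED3 (-0.16, camera adjusted p = 3.16e-42), ED1770 (-0.15, 1.15e-29) and ED1612 (-0.05, 1.66e-08), higher in ED7665 (0.09, 1.46e-15) and ED5071 (0.08, 5.93e-08), and not called in ED4559 (-0.021) and ED10953 (0.0055). With an estimated correlation these had adjusted p of at least 0.219. The proteasome had means from -0.17 to -0.04 in that fit, called lower in all but ED7665 (adjusted p of at least 0.771 with an estimated correlation). Without wild-type replicates 4 and 5 the list means were -0.22 and -0.29, and germline genes then lay 0.73 above wild type (camera adjusted p = 7.95e-06, and adjusted p = 0.698 with an estimated correlation).

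Muscle, nerve and eye genes lay higher against all 6 wild-type arrays but not without the pair high in eggshell genes. The list mean was 0.21 for muscle (1 of 21 higher, Mlp60A by 0.24 ± 0.06, SE, adjusted p = 0.0419, named after its value was seen; 3 adjusted over the list alone), 0.23 for neurons (0 of 18 in limma, 4 adjusted over the list alone) and 0.26 for photoreceptors (0 of 13 in limma, 3 adjusted over the list alone). TpnC73F (0.64) and up (0.62), troponins of muscle, passed within the list, and bt (0.52) and Zasp52 (0.33) did not. The acetylcholine receptor gene nAChRbeta1 (0.54) passed within the neuron list, and Gad1 (0.54), VAChT (0.51) and Snap25 (0.48) did not; inaC (0.51) and rdgC (0.44) passed within the photoreceptor list, and chp (0.37) and Arr1 (0.36) did not. Camera gave adjusted p of 3.73e-04, 0.00336 and 0.00434 for the 3 lists, and adjusted p = 0.880 for each with an estimated correlation. Without wild-type replicates 4 and 5 the list means were -0.04, -0.04 and -0.03. Snap25 itself stood at 8.52 and 9.41 in those 2 arrays and at 10.19 to 10.41 in the other wild-type arrays.

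Detoxification and antioxidant genes had a list mean of 0.08, with 7 higher and none lower, and 12 higher and 2 lower adjusted over the list alone. The glycosyltransferase gene Ugt37A3 rose by 0.75 ± 0.16 (SE, adjusted p = 0.0268) and the cytochrome P450 gene Cyp4e1 by 0.58 ± 0.12 (0.0281), Ugt37A2 (0.64 ± 0.16) passed within the list, and GstE4 (-0.60 ± 0.30) did not. Oxidative phosphorylation genes had a list mean of 0.05, with 0 of 55 called in limma by either adjustment; ND-B8 (0.34), ND-75 (0.20), ND-39 (0.16) and ND-18 (0.14) had the largest differences. Camera gave adjusted p = 0.00916 for detoxification and 0.0130 for oxidative phosphorylation, and adjusted p of 0.880 and 0.914 with an estimated correlation. Without wild-type replicates 4 and 5 the means were -0.01 and -0.05, the latter with adjusted p = 0.00472 in camera and adjusted p = 0.698 with an estimated correlation.

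Ovary lists were not called in the comparison of all arrays. Eggshell and yolk genes had a list mean of -0.83 and a median of -0.09 (camera adjusted p = 0.0870, with yellow-g alone lower adjusted over the list alone, by -1.86), and germline genes a mean of 0.14 (adjusted p = 0.312). The eggshell and yolk mean was -0.27 without wild-type replicate 4. It reversed to 0.43 without wild-type replicates 4 and 5 and was again not called (camera adjusted p = 0.213). Also not called were antimicrobial peptides (-0.18, 0.312; 1 higher and 1 lower adjusted over the list alone), autophagy (-0.06, 0.0821; 1 lower), cuticle (0.07, 0.242; 3 higher), DNA damage and apoptosis (0.01, 0.769), endoplasmic reticulum folding (0.01, 0.720), hemocytes (0.03, 0.519), cytosolic ribosomal proteins (-0.02, 0.0688), ribosome biogenesis (0.06, 0.519) and ubiquitin (-0.02, 0.242), with the list mean and the adjusted p of camera given for each. Dosage compensation had a mean of 0.03 and a median of -0.08 (0.887), other proteases a mean of 0.05 and a median of -0.01 (0.519; 2 higher adjusted over the list alone), and heat shock and chaperones a mean of -0.01 and a median of 0.01 with an upward test (0.960; 1 higher adjusted over the list alone). Turandot, larval fat body, testis and male accessory gland lists had fewer than 5 tested genes and were not tested.

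**Figure D3:**
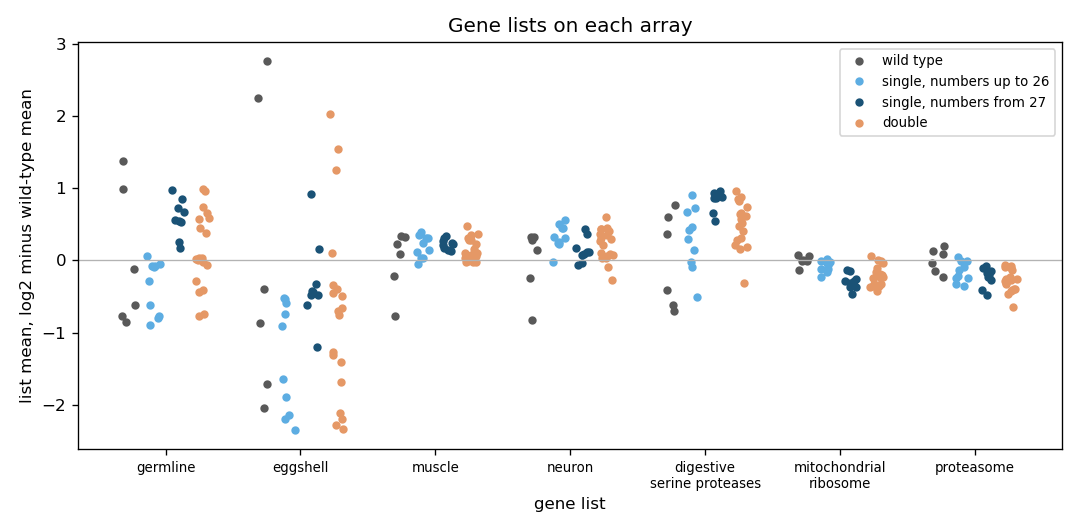
Mean log2 difference from the wild-type mean of 7 gene lists (y axis, 1 point per array, by list on the x axis) in wild type, in single-deletion arrays with numbers up to 26 and from 27, and in double-deletion arrays. Eggshell genes run from -2.04 to 2.77 among the 6 wild-type arrays alone.

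Taken singly, the deletions shared Syt7 and little else that passed. Syt7 rose by 3.70 in ED3 (adjusted p = 5.02e-05), 3.37 in ED10953 (0.000224), 3.12 in ED7665 (0.00325), 3.11 in ED5071 (0.00674) and 2.55 in ED1770 (0.0141); it differed by 1.08 in ED4559 and 0.61 in ED1612, which did not pass. CG14957 rose by 2.96 in ED4559 (0.0481) and 3.37 in ED1770 (0.0183). CG6283 fell by 1.52 in ED4559 (0.00506) and fell by 1.23 in ED10953 (0.0172). CG7900, the gene next to the ED7665 interval, rose by 1.51 in ED7665 (1.76e-05), to 9.34 ± 0.10 (SD, n = 2) from 7.82 ± 0.19 (SD, n = 6). All of these p-values are from limma, with genes inside the deletion's own interval left out.

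In ED10953, CG5953 rose by 2.02 (adjusted p = 0.00154), and Mal-B2, a maltase, fell by 0.69 (0.00429). Its 9 calls (6 higher, 3 lower; 459 unadjusted) also held Arc1 (1.03) and Arc2 (1.05), retrotransposon-derived capsid genes, Mocs1 (0.49) of molybdenum cofactor synthesis, and acetyl-CoA carboxylase, ACC (-0.55). In ED5071, 27 genes passed (23 higher, 4 lower; 1203 unadjusted), among them CG9897 (1.97, adjusted p = 0.0314), GstZ1, a glutathione transferase (-1.14, 0.0347), and PSMG1 (-0.53, 0.0349). In ED1612, Rab3-GAP, a regulator of the vesicle GTPase Rab3, was the single call and fell by 0.62 (0.0227; 825 unadjusted). ED4559 had 4 calls (3 higher, 1 lower; 685 unadjusted), with CG3604 (0.96, 0.00737) and gfzf (0.81, 0.00506) beside those above. ED1770 had 4 (all higher; 476 unadjusted), with CG34043 (0.94) and CG10560 (1.02); ED7665 had 2 (744 unadjusted) and ED3 had 1 (592 unadjusted). Arc1, Arc2, Mocs1, ACC, gfzf, and CG34043 and CG10560 in ED1770 were named after their values were seen.

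These counts rest on few arrays. Leaving out 1 array gave 0 calls for ED5071 (replicate 1; 6 without replicate 2, 9 without wild-type replicate 3 or 6, 59 without wild-type replicate 5), 1 for ED4559 (replicate 3), 1 for ED7665 (either replicate), 0 for ED1612 (replicate 1 or 3, or any wild-type replicate except 4), and 0 for ED1770 (replicate 2 or 3; 1 without replicate 1, 2 without wild-type replicate 3 or 6, 9 without wild-type replicate 5). It gave 5 for ED10953 without replicate 2 and 20 without wild-type replicate 4, and 3 for ED3 without replicate 2 and 2 without wild-type replicate 1.

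The response differed between deletions at 7 of 7184 genes (limma F test, 295 unadjusted). CG7900 was high in ED7665, at 9.34 ± 0.10 (SD, n = 2) against 7.76 to 8.20 in the other deletions (adjusted p = 0.00398). Arc2 stood at 7.98 ± 0.12 (n = 3) in ED10953 and between 6.77 and 6.97 elsewhere (0.0121), and Arc1 at 12.46 ± 0.18 in ED10953 and between 11.41 and 11.96 elsewhere (0.0365). ACC was 10.71 ± 0.10 (n = 3) in ED10953 and 11.23 to 11.55 elsewhere (0.0193). CG18179 ran from 7.64 in ED10953 to 10.25 in ED3 (0.0193), and Syt7 from 5.17 in ED1612 to 8.26 in ED3 (0.0121). The chloride channel gene Cftr, named after its values were seen, was 8.16 ± 0.16 (n = 3) in ED3 and 8.97 to 9.28 elsewhere (0.0365). The count was 2 without ED10953 replicate 2 or ED7665 replicate 2, and 4 without ED10953 replicate 1 or 3, ED4559 replicate 1, ED3 replicate 1 or ED7665 replicate 1; it was 13 without ED1770 replicate 3, 14 with the array-number block and 121 with the germline list as a covariate.

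Flies with 2 deletions were compared with those with 1 to ask whether a second segment adds to the response. No gene outside the intervals passed in limma (0 of 7184; 257 at an unadjusted p under 0.05), and the protease list lay at 0.51 ± 0.31 (SD, n = 19) in doubles and 0.55 ± 0.42 (SD, n = 19) in singles above wild type. Without the 2 double arrays whose mean over all probe sets lay apart, ED4559 with ED1770 (6.21) and ED4559 with ED1612 (6.38), against 6.28 to 6.32 in the other 42 arrays, 1 gene passed. Nor did any gene depart from the sum of the single deletions on average over the 19 double genotypes (0 of 7184 in limma; 765 unadjusted). In tests on simulated data the first of these comparisons found 86 of 100 changes of 0.50 and the second 41 of 100. The simulated genes were independent of each other, so these rates may not hold for the real arrays.

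The series title speaks of proteolysis, so protease levels were set against buffering across the 38 deletion arrays. The 60 genes of both protease lists together had no detectable relation with the 1-copy level on the deposited scaling: r was -0.0307 (permutation p = 0.854) and rho -0.220 (p = 0.184). With arrays recentred on arms X and 3L r was -0.133 (p = 0.405) and rho -0.347 (p = 0.0335, unadjusted). On the deposited scaling r was -0.0864 without the 2 arrays farthest from the median level. Within the array-number groups r was 0.375 (p = 0.113, n = 19) for numbers up to 26 and -0.513 (p = 0.0239, adjusted 0.108, n = 19) for those from 27. In single arrays alone r was -0.185 (permutation p = 0.439) and in doubles 0.170 (p = 0.477). Digestive serine proteases alone had r -0.132 (p = 0.430), and other proteases, cathepsins and metalloproteases among them, had r 0.427 (p = 0.0071, adjusted 0.0639 over 9 relations) and rho 0.422 (p = 0.00876), with r 0.332 without the 2 farthest arrays. All p-values in this paragraph are two-sided.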

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

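In this part the genes that differ between deletions come from a test fixed before the data were examined, and the counts over other splits of the arrays were read after the results were seen. CG7900 (adjusted p = 0.00398, limma F test among the 7 single deletions) lies next to the ED7665 interval and was high in ED7665 alone, at 9.34 ± 0.10 (SD, n = 2). Arc2 (0.0121), Arc1 (0.0365) and ACC (0.0193), capsid-like genes and acetyl-CoA carboxylase, set ED10953 apart from the other deletions. CG18179 (0.0193) was low in ED10953 and high in ED3, and Cftr (0.0365) was low in ED3. Syt7 (0.0121) was high in 5 deletions, and lay nearest to wild type in ED1612 and ED4559. No array stood outside its group by Dixon's ratio in 54 groups of values checked.

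Random splits of the arrays into groups of the real sizes asked whether arrays grouped by chance could give as many calls. Labels were exchanged among the single-deletion and wild-type arrays, and for the test among deletions among single-deletion arrays only. For the mean of the 7 deletions, 2 of 100 splits, the real one among them, gave as many genes as the real 92, with 1339 as the highest other. Splits that ignore array number thus rarely gave as many, which does not exclude chance. With labels exchanged only within the array-number groups, 5 of 100 gave as many, with 1542 as the highest other, and chance cannot be excluded. All wild-type arrays have numbers 1 to 6, below every deletion array. Among numbers up to 26 the count was 3, and with the array-number block 6. Neither setting separates array order from deletion. For the test among deletions, 4 of 100 gave as many as the real 7, with 374 as the highest other. ED5071 and ED7665 have only arrays numbered from 27, so labels were also exchanged within the array-number groups: the real split alone of 100 gave 7 genes, with 3 as the highest other. A count of 7 was thus rare among such splits, but 100 splits cannot exclude chance. The count fell to 2 without ED10953 replicate 2. For the gene lists, 67 of 100 gave as many as the real 9, with 18 as the highest other, and chance cannot be excluded.

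For single deletions against wild type there are 84 splits of 3 and 6 arrays. As many genes as in the real split came from 7 for ED4559 (real 4, highest other 2733), 5 for ED3 (real 1, highest other 3757), 8 for ED1612 (real 1, highest other 2992), 8 for ED1770 (real 4, highest other 4092) and 5 for ED10953 (real 9, highest other 3955). For ED5071 and ED7665, with 2 arrays each, there are 28 splits, and 3 gave as many for each (real 27, highest other 3156; real 2, highest other 3167). Chance cannot be excluded for these counts. For double against single deletions all 100 splits gave at least the real 0, with 0 as the highest other, and for departures from additivity all 100 gave at least the real 0, with 7 as the highest other. Splits that call several times the real count of genes point to a structure of the samples, and a measured one is the ovary: eggshell genes lay 2.77 and 2.26 above the wild-type mean in wild-type replicates 4 and 5, and germline genes 1.37 and 0.99. It is not the only one: the second component of variation held 16.2% of the variance, with a correlation of 0.094 with the germline list. Which structure raised the counts was not tested.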

How the results depend on the processing

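The settings by array number, ovary genes, non-carriers, shifted arrays and the additive fit were chosen after the results were seen; the others were fixed before. Where a result moved, the cause was not tested. Among one-copy results, 128 of 131 comparisons under the fixed settings and 20 of 23 under the added ones were the same. For counts of genes these were 122 of 183 and 7 of 31, for named genes 633 of 740 and 46 of 96, for single lists 203 of 253 and 83 of 115, for counts of lists 9 of 11 and 2 of 5, and for the protease relation 5 of 6 and 1 of 2. A list that was not called and changed sign was counted as the same.

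Without wild-type replicates 4 and 5, high in eggshell genes, the one-copy level was -0.77 for ED5071 and -0.90 for ED7665, each with an exact permutation p of 0.0667, the smallest possible with 4 wild-type arrays. Genes called were 156 for the mean of deletions, 8 for ED1770, 108 for ED5071 and 26 for ED10953. Among the 9 called lists, means reversed for muscle (-0.037), neurons (-0.037), detoxification (-0.011), oxidative phosphorylation (-0.049) and photoreceptors (-0.029). Among lists not called, they reversed for eggshell and yolk (0.43), cuticle (-0.16), heat shock (0.14), other proteases (-0.091), hemocytes (-0.054), cytosolic ribosomal proteins (0.044) and ubiquitin (0.018). Camera at the preset correlation newly called germline, ribosome biogenesis (0.25, adjusted p = 8.15e-05), autophagy, dosage compensation and cuticle. With an estimated correlation 0 lists were called without these 2 arrays.

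With no filter on low values, rho between one-copy level and gene length reversed to -0.0646 and that with expression was -0.677. Counts were 2 for ED3, 0 for ED1612, 15 for ED5071, 14 for ED10953 and 12 for the test among deletions. With a mean of at least 7, ED1770 had 1 call. With the mean of all probe sets, rho with expression was -0.136 and ED4559 had 2 calls. With a mean of at least 8 and non-carriers as the reference, rho with length was 0.0837. Recentring on arms X and 3L gave 0 calls for ED1612. Other proteases alone reversed the relation with the one-copy level (r = 0.427), and arrays numbered from 27 gave r = -0.513.

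Replicate numbers as a block gave 1412 genes for the mean of deletions, 33 for ED4559, 11 for ED3, 14 for ED1612, 7 for ED1770, 2678 for ED5071, 2440 for ED7665, 121 for ED10953 and 184 for the test among deletions. Among the called lists it reversed the means of muscle (-0.039), neurons (-0.032), detoxification (-0.038), oxidative phosphorylation (-0.055) and photoreceptors (-0.011). Taken over all arrays the numbers paired the samples at most in part: 71 pairs of arrays with the same number had a mean correlation of 0.219 after group means were removed, 44 of them over 0.1, from -0.730 to 0.849, and only 5 of 25 arrays were closest to their own number. Other pairs had a mean of -0.0727 (n = 197). The 10 pairs of deletion arrays with number 3 had a mean of 0.653 and all lay over 0.1 (lowest 0.555). These arrays are numbered from 43 to 47 and fall within those from 27. Of pairs with number 1, 13 of 21 lay over 0.1, and 14 of 21 with number 2. Those pairs include ED5071 and ED7665, at array numbers 27, 28, 36 and 42. In the 5 other deletions number 1 is a run from 7 to 12 and number 2 one from 14 to 23. On the second component of variation their numbers 1, 2 and 3 ran from -0.059 to 0.032, 0.070 to 0.135 and -0.283 to 0.039. A block shared by replicates of these deletions is therefore not excluded. By construction the block leaves only the first 3 wild-type replicates, all below the wild-type mean in eggshell genes, to be compared with deletion arrays of the same number, so its counts measure that subset.

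With each deletion fitted alone with wild type, calls were 0 for ED1612, 1 for ED1770, 6 for ED5071 and 4 for ED10953. Among arrays numbered up to 26 the mean of deletions had 3 genes and 17 lists, and with array number as a block 6 genes, 16 lists and 14 genes in the test among deletions. The germline list as a covariate gave 1487 genes and 121 in that test. Without both double arrays of shifted mean, double against single gave 1 gene. Camera with an estimated correlation and fry each called 0 lists. The additive fit over all 44 arrays called 61 genes for ED4559, 32 for ED3, 21 for ED1612, 21 for ED1770, 893 for ED5071, 1400 for ED7665 and 371 for ED10953, and with the array-number block 119, 84, 36, 59, 166, 20 and 565 in the same order.

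Leaving out 1 array moved the one-copy level between -0.83 and -0.80 for ED4559, -0.90 and -0.82 for ED3, -0.87 and -0.81 for ED1612, -0.91 and -0.84 for ED1770, -0.82 and -0.78 for ED5071, -0.89 and -0.84 for ED7665, and -0.89 and -0.79 for ED10953. Lists called ran from 6 (without wild-type replicate 4) to 12 (replicate 3), and the mean of oxidative phosphorylation from -0.020 (replicate 4) to 0.080 (replicate 3). Genes called ran from 20 (wild-type replicate 4) to 160 (ED3 replicate 2) for the mean of deletions, with 44, 50 and 56 without wild-type replicates 1, 2 and 6, 38 without ED5071 replicate 1 and 36 without ED7665 replicate 2. For single deletions they ran from 1 (own replicate 3) to 6 for ED4559, 1 to 3 for ED3 (2 without wild-type replicate 1, 3 without its own replicate 2), 0 to 1 for ED1612 (0 without its own replicate 1 or 3, or any wild-type replicate except 4) and 0 to 9 for ED1770 (1, 0 and 0 without its own replicates 1, 2 and 3; 2, 9 and 2 without wild-type replicates 3, 5 and 6). They ran from 0 to 59 for ED5071 (0 and 6 without its own replicates 1 and 2; 9, 59 and 9 without wild-type replicates 3, 5 and 6), 1 to 3 for ED7665 (1 without either own replicate) and 5 to 20 for ED10953 (own replicate 2, wild-type replicate 4). The test among deletions ran from 2 (ED10953 replicate 2, ED7665 replicate 2) to 13 (ED1770 replicate 3), with 4 without replicate 1 of ED10953, ED4559, ED3 or ED7665, or ED10953 replicate 3.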

Other observations

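All results in this part come from comparisons and tests chosen after the data were seen, most from a fit with 1 term per deletion and the array-number block over all 44 arrays. For ED10953, carried singly or doubly, the fitted differences of all 17 tested eggshell and yolk genes lay below 0 (list mean -1.35, 7 lower over all genes tested, camera adjusted p = 1.34e-05, and adjusted p = 0.825 with an estimated correlation). All 7 tested hemocyte genes rose (list mean 0.72; 1.92e-10, and adjusted p = 0.0720 with an estimated correlation); this list was also called for ED1612 (0.20) and ED4559 (0.12) at the preset correlation, with no gene of it called there (adjusted p of 0.769 and 0.904 with an estimated correlation). Vm26Aa fell by 4.34 (adjusted p = 2.36e-04), to 7.56 ± 2.41 (SD, n = 8) in carriers from 11.99 ± 2.04 (SD, n = 36) in the others, while it ran from 7.50 to 14.26 among the 6 wild-type arrays alone. Vm34Ca fell by 4.31 (1.84e-04), Vm32E fell by 4.13 (0.00236), and the eggshell genes psd and dec fell by 2.27 (0.00296) and fell by 2.75 (0.0210). The later chorion gene Cp15 stood at 5.52 ± 3.13 in carriers and 6.20 ± 3.45 in the others. Per array, against the wild-type mean, the eggshell and yolk list ran from -2.36 to 0.93 in single ED10953 carriers (mean -1.19, n = 3). The other single deletions had means from -1.13 in ED1770 to -0.13 in ED7665. Hml, a hemocyte gene, rose by 1.08 (7.17e-07). CG5953 rose by 1.84 (4.2e-15), and its lowest value in 8 carriers, 14.12, lay above the highest in 36 other arrays, 13.58; it also rose by 0.84 in ED1770 (1.12e-05) and fell by 0.69 in ED5071 (0.0131). This fit called 565 genes for ED10953, and 371 without the block.

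ED1612 removes 1 copy of Vha16-1, which encodes a subunit of the vacuolar proton pump, and of the 19 other pump genes tested 4 passed in its carriers, all lower: Vha100-4 fell by 0.55 (adjusted p = 6.69e-04), Vha100-2 fell by 0.36 (1.22e-07), Vha100-1 fell by 0.33 (1.8e-05) and VhaPPA1-1 fell by 0.19 (0.0170). Camera called the pump genes as a group at the preset correlation (adjusted p = 0.00155) but not with an estimated correlation (adjusted p = 0.926). They did not all move one way: 10 lay above 0 and 9 below, with a mean of -0.08 and a median of 0.00070. The list of detoxification and antioxidant genes was called upward by camera in 6 of 7 deletions, with means of 0.12 in ED10953 (18 genes higher, 1 lower), 0.11 in ED3 (9 and 1) and ED1612 (2 and 0), 0.10 in ED5071 (10 and 1), 0.08 in ED1770 (2 and 0) and 0.05 in ED4559 (3 and 1). In ED7665 the mean was 0.0011, with 0 called. Adjusted p was at most 1.64e-05 in the 6, and at least 0.669 with an estimated correlation. Cftr fell by 0.93 in ED3 (4.63e-14) and fell by 0.38 in ED5071 (0.0159). Zip102B, a zinc transporter gene on chromosome 4, fell by 1.27 in ED3 (5.47e-05), fell by 1.28 in ED7665 (0.0261) and fell by 1.12 in ED5071 (0.0240). Syt7, also on chromosome 4, rose in the same 3 deletions by 2.35 (1.68e-06), 2.05 (0.0188) and 1.89 (0.0131), and in ED10953 by 2.17 (5.01e-06). In ED1770 carriers the antimicrobial peptide gene Def and the transferrin gene Tsf1 rose by 1.39 (0.0418) and 0.70 (0.00144). In ED5071 carriers Hrb87F, an RNA-binding protein gene, fell by 1.03 (7.47e-08). Gene values are limma values of the additive fit, these genes were picked out of its calls, and list p-values were adjusted over all lists and deletions.

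Genes just outside an interval rose in 3 places among 70 neighbours tested. CG7900, 1 gene beyond ED7665, rose by 1.36 (adjusted over neighbours 3.11e-14, limma), to 9.42 ± 0.11 (SD, n = 7) from 8.02 ± 0.23 (SD, n = 37), with no overlap between carriers (lowest 9.27) and the others (highest 8.56). The tetraspanin gene lbm, 1 gene beyond ED1612, rose by 0.71 (5.03e-09), to 7.61 ± 0.14 (SD, n = 9) from 6.94 ± 0.26 (SD, n = 35). CG31288, the third tested gene from ED10953, rose by 0.39 (0.0340). No explanation of these was tested.

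Longer interval genes kept a higher level at 1 copy against wild type. Compression of dim probe sets was checked with expression held, which gave a partial rho of 0.368. Among these filtered genes expression had rho -0.0779 with the level, so holding it could move the relation little and does not decide this. With no filter the relation with length reversed and the level fell strongly with expression, as given above. A candidate explanation is that longer genes lie higher than wild type in deletion flies whatever their copy number, since rho was 0.40 at 2 copies. A response to the lost copy that grows with length stays open: against all arrays with 2 copies rho was 0.121, among genes with a mean of at least 8 it was 0.0837 (permutation p = 0.259), and against 2-copy deletion arrays without wild type it was 0.0377 (p = 0.520). The relation at 2 copies was 0.252 among arrays numbered up to 26 and 0.238 without wild-type replicates 4 and 5.

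Digestive serine proteases lay higher in single deletions than in wild type, by 0.55 per array (permutation p = 0.0188). Ovary stage as the whole cause was tested only with the germline list as a covariate, which gave a difference of 0.50 (SE 0.12). That list differed by only 0.09 between singles and wild type, so the covariate could move the difference little and does not decide this. Eggshell genes, which differed by -0.86, were not tried as a covariate. Jon99Fi stood at 12.15 and 11.47 in wild-type replicates 4 and 5, high in eggshell genes, and at 5.12 to 9.96 in the other wild-type arrays. A batch that follows array number cannot be told apart from the deletions, since wild type is numbered 1 to 6 and every deletion array 7 or higher. Among numbers up to 26 the difference was 0.30 (SE 0.27, p = 0.276, permutation). That is barely past a bound of 0.3 set against this explanation and well within its SE, a margin that was added after these values were seen. Wild type and deletions are separated by array order in that subset too, so it cannot decide this. A response to any lost segment also stays open, as doubles differed from singles by -0.048 (SE 0.12), but in the additive fit with the array-number block 4 of 7 deletions had list means from -0.089 to 0.0020 and the list was called in none of them, in a fit that takes doubles as the sum of singles. Stock background and food intake were not tested.

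Of 119 genes called for ED4559, 52.9% lay on arm 3L, which holds 19.6% of the genes tested (odds ratio 4.76, Fisher's exact test, adjusted p = 1.28e-14); 25 rose and 38 fell, among them CG3819 (up by 3.38, adjusted p = 8.1e-05) and CG8539 (up by 1.89, 1.32e-11). That share argues against a response spread over the genome to the lost genes on 2L. The 2 double arrays of shifted mean are argued against too, since single arrays alone placed 37 of the 100 genes with the smallest p on 3L. A candidate explanation is a sequence difference on arm 3L that came with the ED4559 stock, a hypothesis with no genotype data behind it: single and double arrays apart placed 37 and 38 of 100 there, and 199 of 223 genes on 3L with an unadjusted p under 0.05 in doubles had the same sign in singles (89.2%, against 81.1% outside 3L). Calls of ED10953 also gathered on an arm, 141 of 565 on 2L (odds ratio 1.57, Fisher adjusted p = 3.23e-04), while 9 of 20 for ED7665 on 3L did not pass (3.35, 0.0517), and the share of calls on 3L was at or above the share tested there in all 7 deletions.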
